A study of Danio rerio with 4 samples.

How the data were processed

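The measurement was droplet-based single-cell RNA sequencing (10x Genomics) of photoconverted cells sorted from brain tissue of Tg(elavl3:NLS-CaMPARI2) zebrafish larvae, in 2 libraries from larvae shown moving and 2 from larvae shown stationary patterns. Per the labels' protocols, each library pooled the tissue of many larvae, the eyes and the tissue in front of the habenula and behind the otolith were removed, the tissue was digested with papain and red cells were sorted by fluorescence. The authors deposited, for each library, a matrix of raw counts of UMIs per gene and barcode with no normalization. The matrices were written by Cell Ranger 6.0.1, per the file headers. Cell Ranger, Seurat and the genome build GRCz11 are named per the submitters' processing notes. The files list 36352 features including the reporter, and 242 symbols are repeated. The annotation and the filters behind the list of barcodes are not given in the sources used here. Genomic positions are not used here. Symbols and identifiers are those of the feature files.

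Libraries were grouped by condition and numbered by batch from the sample titles. The files held 3735, 4818, 3122 and 3884 barcodes for moving libraries 1 and 2 and stationary libraries 1 and 2. Barcodes with at least 500 detected genes and at most 10% of counts from genes with the mt- prefix were kept as cells. Scrublet, run through Scanpy 1.11.5, marked 0, 1, 0 and 1 cells as doublets. That is under 0.5%, so the caller was taken not to have worked, all cells were kept and doublets remain. An alternative removed the cells with the highest scores, at 0.8% per 1000 cells. Counts were scaled to 10000 per cell and log-transformed. The 2000 variable genes were chosen without 217 stress, activity, mitochondrial, haemoglobin and ribosomal genes. Clustering used 40 principal components, 15 neighbours and Leiden resolution 2 (the igraph version, run through Scanpy), with no integration of libraries. A cluster could be named when at least 3 markers of a type were raised at least 2-fold and found in at least 10% of its cells. The name was withheld on ties, and where its 10 leading genes held no marker of that type or more markers of other types. It was also withheld where the transmitter markers went against the type. In all, 32 of 55 clusters stayed unnamed. Clusters were called glutamatergic-like or GABAergic-like when the markers of that class exceeded those of the other 4-fold, at least 40% of cells held a marker of that class and at most 25% held a marker of the other. The broadly expressed genes slc6a1a and slc6a1b were left out of that score. These thresholds were set after the data were seen, and clusters that passed the ratio but were held out made up 4.57%, 5.78%, 4.71% and 5.46% of the libraries.

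Cells are not replicates, so raw counts were summed per library, per class and per cluster with at least 30 cells in every library. The sums were tested with edgeR 4.0.16 (TMM factors, filterByExpr, glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Cells per cluster were tested the same way against the number of cells per library, without TMM factors. The class test fitted the library as a term. Gene lists were tested with camera on voom values in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry, whose p asks whether the genes of a list move one way on balance. List members that the feature files do not name were not tested. CPM were computed from the deposited counts by dividing by the total over the kept cells of the library or class. With 2 libraries against 2 an exact permutation test of a single value cannot give a p below 0.333, and by chance 33.3% of genes would show no overlap between the groups. P-values therefore come from models fitted across genes. Standard deviations are over libraries, floors are 3 counts over a group, and floors cover counting error only. Standard errors (SE) are approximations, taken as the absolute log2 fold change divided by the square root of edgeR's F statistic.

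The design, the tests, the gene lists, the cell type markers and the rule for named genes were fixed before the data were examined. For whole libraries the rule took up to 12 genes in each direction past the threshold, and within a class up to 5, by the largest fold change among those with a mean CPM of at least 10 and no overlap between conditions. Fewer were filled up to 5 in each direction by the smallest unadjusted p, as values not passing. It also took the 5 smallest p of the class test, the 10 smallest adjusted p of single clusters and, for each list, its called members or otherwise its 2 members of highest mean CPM, with nkx1.2lb, mafaa and tcf7l2 in any case. Not every gene that the rule took is reported here. For clusters it took those past the threshold, or otherwise the 3 smallest p in each direction. The alternatives were DESeq2 1.42.0, other scaling factors, no filter on low counts, other cell filters and other clusterings. A further alternative left out clusters named as a non-neuronal type. Only the skin-like cluster bore such a name, so all unnamed clusters were kept. The remaining alternatives were a standardised makeup of clusters, other list and share tests, the batch as a block and leaving out each library. Added after seeing the data were the removal of the highest doublet scores, of barcodes over 30000 UMIs and of clusters lacking moving cells, the crossed pairing, the block with an estimated correlation and, for lists, leaving out each library with an estimated correlation.

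The titles mark same-numbered libraries as 1 batch. On balance across genes such libraries did not deviate together. Over 8493 genes with a mean CPM of at least 10, the correlation across genes of their deviations from the group means was -0.212. Single values could still follow the batch. The heat shock list took 9.66% and 10.6% of the UMIs in batch 1 and 13.3% and 13.5% in batch 2, moving first.

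Each test was checked on simulated counts in which 200 genes were changed by known folds. With the spread estimated from these libraries, edgeR on whole libraries recovered 0%, 19.4% and 69.7% of genes changed 2-fold, 4-fold and 16-fold among 18861 genes, with 13 false calls. With a dispersion of 0.01 it recovered 73.1%, 89.6% and 98.5% among 19098 genes, with 10 false calls. At the same folds and the estimated spread it recovered 5.97%, 80.6% and 100% for glutamatergic-like clusters among 15935 genes, with 5 false calls. For GABAergic-like clusters it recovered 23.9%, 97.0% and 100% among 14284 genes, with 12 false calls, and for the class test 1.49%, 43.3% and 100% among 15900 genes, with 11. A single cluster simulated with a dispersion of 0.01 gave 41.8%, 94.0% and 100% among 9330 genes. Whole-library genes were drawn from all filtered genes and changed in either direction. Genes of the class, class-test and single-cluster checks were drawn only above a minimum mean count and only raised in the moving libraries. Their rates therefore cannot be compared with the whole-library rates. They do not cover genes with low counts or genes lower in the moving libraries. Of 3 clusters changed in share at each fold among 55, edgeR recovered 0%, 100% and 100%. Camera recovered 100% of 4 lists changed 2-fold among 20. Camera was simulated only with the preset correlation and with genes drawn independently. That check therefore covers neither correlated genes nor the estimated correlation, and fry was not simulated.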

Results

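The series holds single-cell RNA sequencing of brain cells from zebrafish larvae carrying NLS-CaMPARI2 in all neurons, under the elavl3 promoter. CaMPARI2 is a calcium sensor that turns from green to red when light of the right wavelength falls on an active neuron, so a red nucleus marks a neuron active during the exposure. Larvae received the light while viewing either moving or stationary patterns, and red cells were sorted for 10x Genomics libraries. There were 2 libraries per condition, and each of the 2 batches held 1 library of each condition. The deposited totals were 15806195 and 18853350 unique molecular identifiers (UMIs) in moving libraries 1 and 2, and 14991479 and 19920016 in stationary libraries 1 and 2. After filtering these held 3345, 4640, 2890 and 3737 cells, with medians of 4233, 3599.5, 4538 and 4982 UMIs per cell. Nothing in the labels says that the pools of larvae were otherwise independent, so the p-values measure only the spread between these samples, which may be technical.

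The cells formed 55 clusters. Of these, 28 were called glutamatergic-like from vesicular glutamate transporter genes and 10 GABAergic-like from genes of GABA synthesis and vesicular transport. Glutamatergic-like clusters held 45.3% ± 2.41 of the cells of the moving libraries and 47.9% ± 0.408 of the stationary libraries (SD, n = 2 each). GABAergic-like clusters held 34.0% ± 3.05 and 28.5% ± 1.87. Transcripts of the reporter stood at 1744 and 1737 counts per 1000000 UMIs (CPM) in the moving and 1293 and 1791 CPM in the stationary libraries. A skin-like cluster, marked by keratin genes such as krt4, held 0.299% and 1.64% of the moving and 1.31% and 0.856% of the stationary libraries. Photoreceptor markers took 5.86e-04, 4.91e-04, 5.34e-04 and 6.27e-04% of the UMIs of moving libraries 1 and 2 and stationary libraries 1 and 2. Marker genes of red blood cells took 0.00107, 9.67e-04, 7.98e-04 and 0.00122% in the same order.

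The first comparison asked which genes differed between photoconverted cells of the 2 conditions, as possible markers of neurons that respond to optic flow. LOC100535857, an uncharacterised locus (identifier LL0000040463), stood at 0.772 and 1.12 CPM in the moving libraries and 27.7 and 30.1 CPM in the stationary libraries, a log2 fold change of -4.92 ± 0.36 (SE, n = 2 each). The unnamed loci CU076099.1 and CT025897.1 and the microRNA gene mir130b lay in the same direction, with log2 fold changes of -3.21 ± 0.34, -2.87 ± 0.33 and -2.40 ± 0.28. A single cell held 170 of 453 CT025897.1 UMIs in stationary library 1. In the clusters lacking moving cells, described below, these 3 genes stood at 246, 216 and 133 CPM. In the other cells of stationary libraries 1 and 2 CU076099.1 stood at 18.9 and 11.7 CPM, and CT025897.1 at 21.1 and 15.0 CPM. Over both libraries mir130b stood at 19.0 CPM in those other cells. Transcripts of npvf, which encodes an RFamide neuropeptide precursor, had no UMI in the moving libraries and 31.2 and 13.9 CPM in the stationary libraries, at least 244-fold higher against a floor of 3 counts over the moving group. A single cell held 458 of 462 npvf UMIs in stationary library 1, and another held 275 of 276 in stationary library 2. In the opposite direction, the ferritin heavy chain-like genes fthl28 and fthl30, of the iron storage family, stood at 45.1 ± 26.1 against 13.3 ± 0.139 CPM and 19.0 ± 5.47 against 6.93 ± 1.49 CPM, moving first (SD, n = 2). In moving library 2, 160 of 499 fthl28 and 151 of 428 fthl30 UMIs lay in 1 cell for each gene. The chemokine gene cxcl12a stood at 43.4 ± 3.10 against 23.3 ± 5.76 CPM and the unnamed locus BX511246.1 at 25.5 ± 18.3 against 6.62 ± 2.29 CPM. For nme2b.2, of the nucleoside diphosphate kinase family, the values were 59.4 ± 76.6 against 2.64 ± 0.663 CPM, and 1 cell held 2037 of 2126 UMIs in moving library 2. The fthl genes belong to a family of similar copies, so reads may have been split between them.

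None of these genes passed the test. edgeR called 0 of 19486 genes, with 297 at an unadjusted p under 0.05 and a smallest adjusted p of 0.294. Of those 297 genes, 66 were higher and 231 lower in the moving libraries. Without the clusters lacking moving cells edgeR also called 0, with 255 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999993. DESeq2, run with those clusters, called 47 genes, 3 higher and 44 lower in the moving libraries. The direction of edgeR's calls turned with the library left out: 39 genes were higher and 3 lower in the moving library without moving library 1, and 5 higher and 39 lower without moving library 2. Without stationary library 2, 0 were higher and 16 lower, and without stationary library 1 edgeR called 0 (with 156 at an unadjusted p under 0.05). By the rule that chose them, all 10 named genes had both moving libraries on the same side of both stationary libraries, so each had the same direction within both batches.

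**Figure D1:**
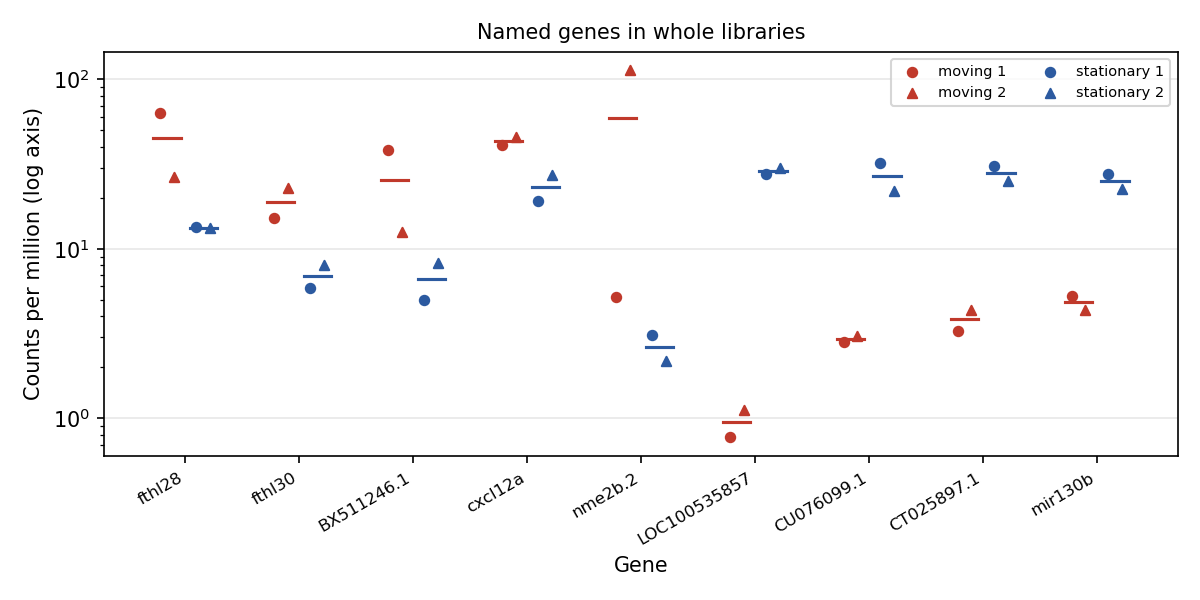
CPM (log axis) in each library for the genes named in the whole-library comparison, apart from npvf, which had no UMI in the moving libraries; circles are batch 1, triangles batch 2, red moving, blue stationary, and lines are group means. LOC100535857 lies at 0.772 and 1.12 CPM in the moving and 27.7 and 30.1 CPM in the stationary libraries, and no gene shown passed edgeR's threshold.

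The second comparison tested 17 gene lists. The mitochondrially encoded genes, which code for parts of the respiratory chain and of ATP synthase, had all 12 measured members lower in the moving libraries, with a median log2 fold change of -0.74 and an adjusted p of 1.08e-16 from camera with a preset correlation. With an estimated correlation camera gave p = 0.0582 and adjusted p = 0.733, and the adjusted p from fry was 0.844. Over all alternatives and tools the adjusted p ran from 1.02e-17 to 0.964. edgeR called 0 members over all genes and 0 adjusted over the list alone, with 8 at an unadjusted p under 0.05. The cytochrome c oxidase gene mt-co2 stood at 3292 and 2276 CPM in the moving and 4644 and 4404 CPM in the stationary libraries, and the cytochrome b gene mt-cyb at 1507 ± 129 against 2339 ± 310.3 CPM (SD, n = 2). The list took 0.840% of the UMIs of moving library 1 against 1.38% of stationary library 1, and 0.728% against 1.19% in batch 2. Of 46 clusters with at least 10 cells in every library, all 46 had a lower mean share in the moving libraries. In 43 of them both moving libraries lay below both stationary libraries. The thalamic or pretectal GABAergic-like cluster had 0.894% and 0.653% in the moving and 1.14% and 1.21% in the stationary libraries.

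**Figure D2:**
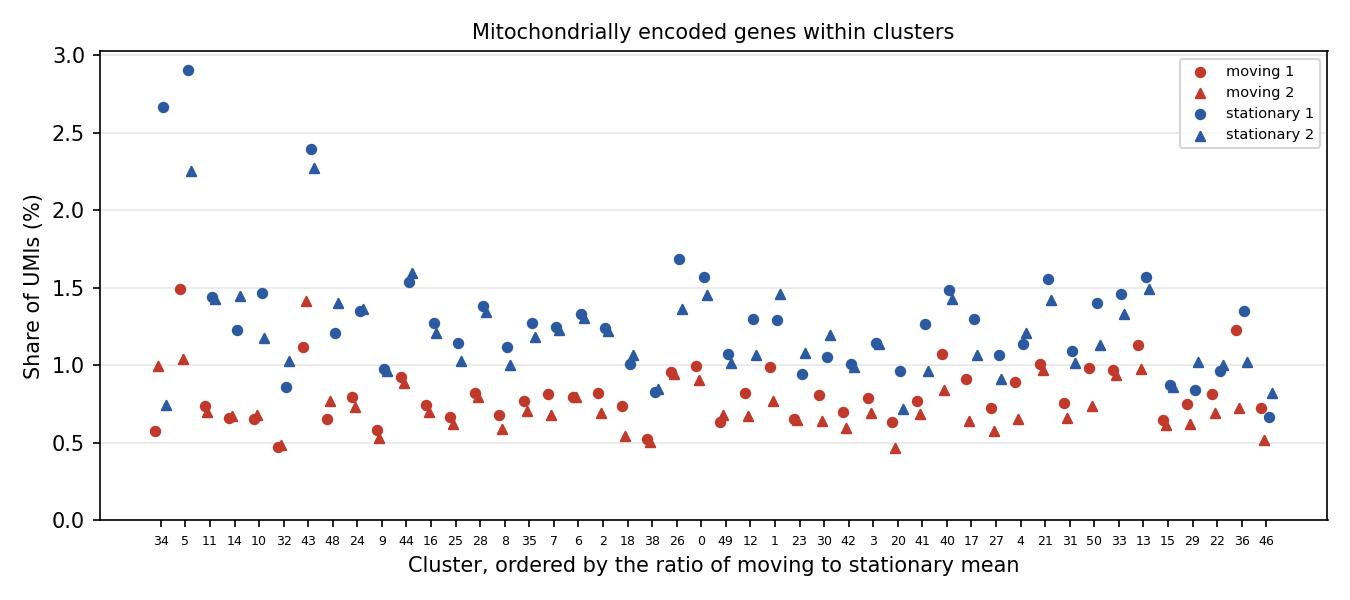
Share of UMIs (%) from the mitochondrially encoded list in each of 46 clusters, 1 point per library (circles batch 1, triangles batch 2, red moving, blue stationary), with clusters ordered by the ratio of the group means. The log2 of that ratio runs from -1.12 to -0.26, and the groups overlap in clusters 34, 36 and 46.

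Activity-regulated and stress genes gave no list that passed. Of 34 immediate early genes, which neurons transcribe soon after activity, 16 were higher and 18 lower in the moving libraries (median log2 fold change -0.018, camera adjusted p 0.343). The transcription factor genes fosab and jun stood at 2387 ± 1379 against 1836 ± 265 and 1838 ± 466 against 1783 ± 143 CPM, moving first (SD, n = 2). Among 24 later activity-regulated genes 8 were higher and 16 lower (median -0.073, camera adjusted p 0.407), with the secretory granule genes scg2b at 1815 ± 338 against 1901 ± 39.4 and vgf at 815 ± 41.2 against 868 ± 75.1 CPM. The heat shock and dissociation stress list had 7 higher and 13 lower (median -0.11, camera adjusted p 0.138). It took 9.66% and 10.6% of the UMIs of the moving and stationary library of batch 1, and 13.3% and 13.5% in batch 2. Its chaperone genes hsp90aa1.2 and hsp70l stood at 30610.2 ± 12353 against 35077 ± 1209 and 31026 ± 401 against 28849 ± 2858 CPM. The unfolded protein response list had 11 higher and 6 lower, a median of 0.027, a mean of -0.028 and a camera direction below 0 (adjusted p 0.473), with the chaperone gene hspa5 at 1335 ± 444 against 1257 ± 323 and the transcription factor gene xbp1 at 1088 ± 261 against 1100.1 ± 0.738 CPM. In each of these lists edgeR called 0 members over all genes and 0 adjusted over the list alone, with 1 immediate early gene and 0 members of the others at an unadjusted p under 0.05. Single libraries moved these medians. Without moving library 1 the medians were, for the heat shock list 0.17 (adjusted p 0.0347), the unfolded protein response list 0.17 (adjusted p 0.0166) and the immediate early genes -0.15 (adjusted p 0.0183). Without moving library 2 they were, for the heat shock list -0.46 (adjusted p 3.64e-06) and the unfolded protein response list -0.40 (adjusted p 6.30e-04), and without stationary library 1 the heat shock list had -0.16 (adjusted p 0.0381), all from camera. With an estimated correlation these calls were lost, with adjusted p from 0.738 to 0.964. Few libraries enter that estimate, and it passed 0 lists in each fit, so the loss leaves these calls undecided.

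Lists of receptors, channels and synaptic genes had more members higher than lower in the moving libraries, without passing. Ionotropic glutamate receptors had 17 of 23 higher (median log2 fold change 0.087, camera adjusted p 0.310), with the NMDA receptor genes grin1b at 197 ± 111 against 169 ± 62.1 and grin1a at 124 ± 29.8 against 97.6 ± 19.2 CPM (SD, n = 2). GABA-A and glycine receptors had 13 of 21 higher (median 0.043, camera adjusted p 0.310), with gabrb4 at 191 ± 72.6 against 183 ± 5.17 CPM. Voltage-gated channels had 26 of 35 higher (median 0.13, camera adjusted p 0.138), with the sodium channel genes scn1lab at 289 ± 241 against 309 ± 48.9 and scn1ba at 266 ± 96.9 against 285 ± 38.0 CPM. Presynaptic release genes had 22 of 27 higher (median 0.092, camera adjusted p 0.153), with the vesicle fusion genes vamp2 at 1477 ± 72.1 against 1469.8 ± 10.4 and snap25a at 1434 ± 311 against 1201 ± 74.9 CPM. Calcium-binding proteins had 22 of 29 higher (median 0.15, camera adjusted p 0.0719), with the calmodulin genes calm1a at 1435 ± 35.8 against 1239.8 ± 22.0 and calm2b at 779 ± 99.3 against 781 ± 46.1 CPM. Neuronal identity genes had 15 of 19 higher (median 0.19, camera adjusted p 0.0884), with elavl3 at 4145 ± 2012 against 3154 ± 110.4 and the stathmin gene stmn1b at 3132 ± 215 against 2587 ± 269 CPM. In these lists edgeR called 0 members over all genes and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05. Without the skin-like cluster the calcium-binding proteins passed camera (adjusted p 0.0412), and with an estimated correlation over all cells their adjusted p was 0.733. These medians also depended on single libraries. Without moving library 1 camera gave the presynaptic list a median of -0.18 (adjusted p 0.0183). Without moving library 2 the medians were, for presynaptic genes 0.30 (adjusted p 4.43e-04), neuronal identity genes 0.36 (adjusted p 9.64e-04), calcium-binding proteins 0.16 (adjusted p 0.0172) and GABA-A and glycine receptors 0.19 (adjusted p 0.0442). Without stationary library 2 they were, for voltage-gated channels 0.29 (adjusted p 0.00139), neuronal identity genes 0.25 (adjusted p 0.0200), presynaptic genes 0.18 (adjusted p 0.0200), glutamate receptors 0.22 (adjusted p 0.0200) and calcium-binding proteins 0.14 (adjusted p 0.0301). All of these calls were lost with an estimated correlation in the same fits (adjusted p 0.738 to 0.941).

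Metabolic, clock and transmitter lists also missed the threshold. Glycolysis genes had 13 of 21 higher, a median log2 fold change of 0.020, a mean of -0.23 and a camera direction below 0 (adjusted p 0.407), with the enzyme genes gapdhs at 3393 ± 69.4 against 3299 ± 205 and tpi1b at 1402 ± 168 against 1308 ± 36.4 CPM (SD, n = 2). Nuclear genes of oxidative phosphorylation had 17 of 26 higher (median 0.066, camera adjusted p 0.214), with the cytochrome c gene cycsb at 1496 ± 99.4 against 1289.5 ± 47.8 and the ATP synthase gene atp5f1b at 721 ± 5.73 against 741 ± 66.7 CPM. Clock and light-responsive genes had 19 of 30 higher (median 0.22, camera adjusted p 0.0861), with nfil3-5 at 396 ± 219.8 against 464 ± 13.9 and tefa at 445 ± 108 against 328 ± 76.9 CPM. Neurotransmitter genes had 14 higher and 14 lower, a median of 0.010, a mean of -0.12 and a camera direction below 0 (adjusted p 0.274), with the GABA synthesis gene gad2 at 615 ± 291 against 515 ± 67.5 and the GABA transporter gene slc6a1a at 519.8 ± 214 against 418 ± 76.0 CPM. Neuropeptides had 17 higher and 20 lower (median -0.051, mean -0.52, camera adjusted p 0.0719), with adcyap1b at 1113 ± 143 against 1098 ± 140.4 and the hypothalamic peptide gene agrp at 497 ± 491 against 589 ± 134 CPM. edgeR called 0 members of these lists over all genes, and adjusted over the list alone it called 1 neuropeptide gene, npvf. At an unadjusted p under 0.05 lay 3 neuropeptide, 2 glycolysis, 1 neurotransmitter, 0 nuclear and 0 clock genes. Without the skin-like cluster the neuropeptides and the clock genes passed camera (adjusted p 0.0412 each). With an estimated correlation over all cells the camera adjusted p of both was 0.733. With the batch as a block the neuropeptides passed camera (adjusted p 3.27e-04), and with an estimated correlation beside the block the adjusted p was 0.793. Without moving library 1 camera gave the neurotransmitter list a median of -0.29 (adjusted p 2.26e-04), and without stationary library 1 of -0.063 (adjusted p 0.0436). Without moving library 2 the median of the neuropeptides was -0.39 (adjusted p 4.43e-04), and without stationary library 2 the medians of the neuropeptides and the clock genes were -0.19 (adjusted p 0.00260) and 0.30 (adjusted p 0.00297), all from camera. In the same fits with an estimated correlation the adjusted p ran from 0.738 to 0.964.

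Transcription factors of the pretectum and its neighbours, the tissue that the dissection aimed to enrich, had 50 of 79 members higher in the moving libraries (median log2 fold change 0.099, camera adjusted p 0.310). edgeR called 0 of them over all genes and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05. The list took 0.623% and 0.314% of the UMIs of the moving and 0.361% and 0.405% of the stationary libraries. The homeobox gene zfhx4 stood at 486 ± 322 against 338 ± 67.2 CPM (SD, n = 2). The Wnt pathway factor gene tcf7l2 stood at 567 and 229 CPM in the moving and 209.9 and 273 CPM in the stationary libraries. The homeobox gene nkx1.2lb stood at 9.90 ± 1.26 against 9.72 ± 2.27 CPM and the bZIP factor gene mafaa at 5.10 ± 3.89 against 3.24 ± 3.06 CPM. Without moving library 1 camera gave the list a median of -0.27 (adjusted p 7.13e-06), without moving library 2 0.34 (adjusted p 9.49e-07) and without stationary library 2 0.21 (adjusted p 0.0284). With an estimated correlation the adjusted p was 0.857, 0.738 and 0.756 in the same order, and 0.787 with all libraries. Over all 17 lists, camera passed 7 lists without moving library 1, 9 without moving library 2, 3 without stationary library 1 and 9 without stationary library 2, the mitochondrially encoded list among them each time, and with an estimated correlation 0 in each of the 4 fits, with 0 at an unadjusted p under 0.05.

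The third comparison asked whether cell types differed in their share of the sorted cells. An alternative clustering left out the 297 genes at an unadjusted p under 0.05 between the conditions. Those genes were taken from these same libraries, so clusters set apart by them could hardly form. A lack of calls there therefore excludes no difference in share. In it edgeR called 0 of 54 clusters, with 1 at an unadjusted p under 0.05. That cluster was serotonergic-like, marked by the serotonin synthesis gene tph2 and the serotonin transporter gene slc6a4a, and held 0.0598% and 0.539% of the moving and 0.865% and 1.07% of the stationary libraries (edgeR adjusted p = 0.864). Next by p were a cluster led by adcyap1a and calb2a, with 0.628% and 0.496% against 1.14% and 1.34%, and a cluster led by clic5b, with 0.149% and 0.216% against 0.346% and 0.482%. On the other side, the habenular-like cluster, marked by gng8 and kctd12.1, held 5.98% and 1.49% of the moving and 3.15% and 1.66% of the stationary libraries. A cluster led by pyyb and p2rx3a held 0.688% and 0.862% against 0.727% and 0.294%, and a cluster led by htr3a and ptger4a 0.568% and 1.14% against 0.796% and 0.401%. The dissection border lay at the habenula, which can set the share of habenular cells.

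In the clustering that kept those genes, edgeR called 3 of 55 clusters, and limma on logit shares also called 3. Clusters 47, 53 and 54 held 92 and 157, 19 and 18, and 8 and 12 cells of stationary libraries 1 and 2 (edgeR adjusted p 1.47e-11, 1.18e-05 and 5.23e-04). They held no moving cell, which allows a share of up to 0.0376% of the moving cells in each. Their 306 cells made up 4.12% and 5.00% of the stationary libraries. LOC100535857 is among the leading genes of all 3, so their sizes are not separate evidence. The granule-like clusters, marked by cbln12 and fat2, held 6.70% and 7.48% of the moving and 9.38% and 9.55% of the stationary libraries, cluster 53 included. The thalamic or pretectal GABAergic-like cluster, marked by tal1 and gata3, held 12.0% and 6.68% against 6.16% and 7.47% (edgeR adjusted p 0.972). The unnamed cluster 3 also had tal1 and gata3 among its leading genes, and held 2.33% and 2.72% against 1.35% and 2.49%.

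**Figure D3:**
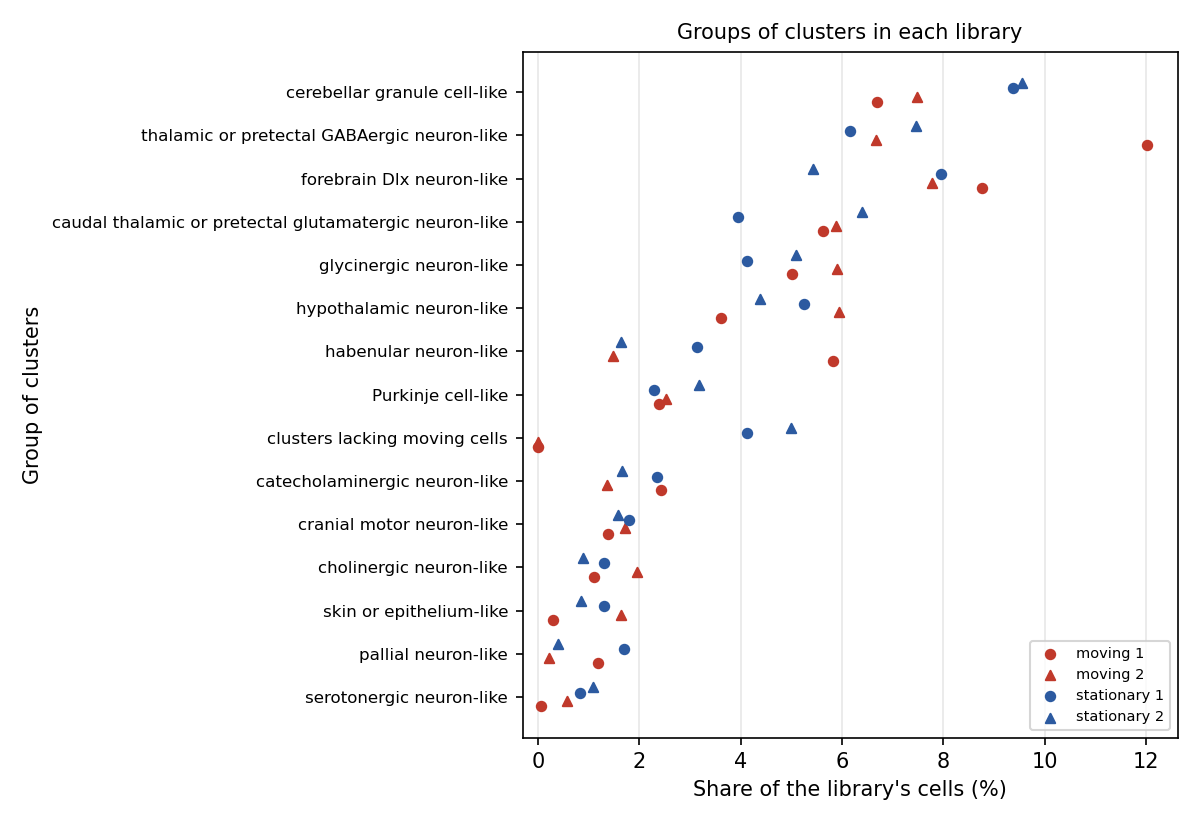
Share of each library's cells (%) in groups of clusters named from marker genes and in the clusters lacking moving cells, 1 point per library (circles batch 1, triangles batch 2, red moving, blue stationary). The clusters lacking moving cells held 4.12% and 5.00% of the stationary libraries, and the thalamic or pretectal GABAergic-like cluster held 12.0% of moving library 1 and 6.68% of moving library 2.

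The fourth comparison took each transmitter class alone. In the glutamatergic-like clusters LOC100535857 fell in the moving libraries, to 0.870 and 0.742 CPM from 24.8 and 27.4 CPM in the stationary libraries (log2 fold change -5.02 ± 0.38, edgeR adjusted p = 0.0244, n = 2 each). It was the 1 gene called of 15634, with 252 at an unadjusted p under 0.05, and its highest single cell held 11 of 162 and 10 of 249 UMIs in the stationary libraries. Of the genes that did not pass, the growth hormone receptor gene ghrb (identifier LL0000011304) stood at 3.50 ± 0.581 against 27.4 ± 1.01 CPM, moving first (SD, n = 2), si:ch73-215f7.1 at 7.06 ± 0.884 against 31.0 ± 0.411 CPM and si:dkey-244a7.1 at 23.7 ± 0.746 against 99.3 ± 26.0 CPM. A single cell held 75 of 183 and another 63 of 242 ghrb UMIs in the stationary libraries. Transcripts of npvf had no UMI in the moving libraries and 70.4 and 30.3 CPM in the stationary libraries, at least 235-fold higher, with 458 of 459 and 275 of 275 UMIs in 1 cell each. In the opposite direction, the neuromedin U gene nmu (identifier LL0000020435) stood at 69.9 ± 29.6 against 8.68 ± 0.339 CPM (edgeR adjusted p 0.194), but with the highest doublet scores removed its log2 fold change was -1.21, and without barcodes over 30000 UMIs it was 0.83. Of its 1072 moving UMIs, 921 and 953 lay in cells outside the class once the cells were clustered again for these 2 settings. The ferritin-like genes fthl31 and fthl28 stood at 29.8 ± 5.98 against 10.4 ± 0.391 and 39.4 ± 29.1 against 11.2 ± 0.844 CPM, the nociceptin precursor gene pnocb at 14.9 ± 4.59 against 5.70 ± 2.14 CPM, with 38 of 125 UMIs of moving library 1 in 1 cell, and BX511246.1 at 31.5 and 11.8 CPM in the moving and 4.91 and 6.60 CPM in the stationary libraries.

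Clusters 53 and 54 belong to the glutamatergic-like class, and LOC100535857 and ghrb are among the leading genes of cluster 53. Without the clusters lacking moving cells the log2 fold change of LOC100535857 was -4.13 (edgeR adjusted p 0.0893; 7.61e-14 to 0.0893 over all alternatives and tools), and edgeR called 0 genes, with 210 at an unadjusted p under 0.05. DESeq2, run with those clusters, called 26. With the batch as a block edgeR called 6: LOC100535857, c16h2orf66, ghrb, nms, nmu and npvf, where nms was chosen after its values were seen and had 262 of 508 and 104 of 132 UMIs in 1 cell of each stationary library. Leaving out moving library 1 or 2 gave 12 or 126 genes, and leaving out stationary library 1 or 2 gave 30 or 35, with LOC100535857 called each time.

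In the GABAergic-like clusters urp1, which encodes a urotensin II-related peptide precursor (identifier LL0000031681), was the 1 gene called of 14339, with 240 at an unadjusted p under 0.05. It stood at 1.38 and 0.351 CPM in the moving and 82.1 and 47.6 CPM in the stationary libraries (log2 fold change -6.26 ± 0.53, edgeR adjusted p = 0.0408, n = 2 each). A single cell held 314 of 316 urp1 UMIs in stationary library 1, and another held 271 of 273 in stationary library 2. Of the genes that did not pass, the aldolase gene aldoca, expressed in Purkinje cells, stood at 4.03 ± 4.24 against 35.5 ± 5.80 CPM, moving first (SD, n = 2). A single cell held 119 of 121 aldoca UMIs in stationary library 1, 170 of 227 in stationary library 2 and 33 of 40 in moving library 2. The microRNA gene mir130b stood at 4.77 ± 1.77 against 16.6 ± 1.14 CPM, CT025897.1 at 4.43 ± 0.0585 against 15.8 ± 3.29 CPM and si:ch73-215f7.1 at 7.64 ± 0.381 against 19.4 ± 0.234 CPM. In the opposite direction cxcl12a stood at 29.8 ± 11.9 against 10.8 ± 3.20 CPM, with 105 of 222 UMIs of moving library 1 in 1 cell, fthl31 at 27.5 ± 12.3 against 9.35 ± 3.31 CPM and zgc:65851 at 62.6 ± 31.4 against 24.6 ± 0.473 CPM. BX511246.1 stood at 48.0 and 14.9 CPM in the moving and 5.71 and 10.3 CPM in the stationary libraries, and igfbp6b, of the insulin-like growth factor binding protein family, at 24.5 ± 6.25 against 11.1 ± 1.60 CPM, with 44 of 117 UMIs of moving library 1 in 1 cell.

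The urp1 call was lost with upper-quartile factors (-6.24, edgeR adjusted p 0.0512; 8.84e-43 to 1.000 over all alternatives and tools) and with the highest doublet scores removed (-6.42). It was also lost with a stricter cell filter (-1.50) and without barcodes over 30000 UMIs (-0.44), and with a looser filter the log2 fold change was 1.01. DESeq2 called 1 gene, urp1, and edgeR with the batch as a block called 3: urp1, aldoca, whose UMIs lay mostly in 1 cell of each stationary library, and pvalb8, the last chosen after its values were seen. Leaving out moving library 1 or 2 gave 12 or 668 genes, and leaving out stationary library 1 or 2 gave 2 or 3, with urp1 called each time.

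The fifth comparison fitted 32 clusters singly. In the glycinergic-like cluster 0, urp1 was the 1 call of 156640 tests (log2 fold change -9.42 ± 0.73, edgeR adjusted p = 0.0305), with 4178 tests at an unadjusted p under 0.05. A single cell held 314 of 314 UMIs in stationary library 1 and another 271 of 272 in stationary library 2. At Leiden resolution 1, edgeR's 1 call of 153234 tests was npvf in place of urp1 (adjusted p 0.0274). The next by adjusted p at the resolution used throughout did not pass. In the glutamatergic-like cluster 9, npvf had 458 of 458 and 275 of 275 UMIs in 1 cell of each stationary library (edgeR adjusted p 0.0507), and c16h2orf66, an uncharacterised reading frame (identifier LL0000003878), had 3508 of 3519 and 424 of 424. In the same cluster nmu stood at 570.4 and 627 CPM in the moving and 32.5 and 73.1 CPM in the stationary libraries (edgeR adjusted p 0.297). The vasoactive intestinal peptide gene vipb had 168 of 171 and 52 of 53 UMIs in 1 cell of each moving library in the habenular-like cluster 16. The corticotropin-releasing hormone gene crhb had 85 of 85 and 50 of 50 in cluster 20. The cortistatin gene cort stood at 144 and 219 CPM in the moving libraries in cluster 5 and had no UMI in the stationary libraries, with 21 of 31 and 43 of 47 UMIs in 1 cell of each moving library. In the Purkinje-like cluster 40, the log2 fold changes of BX005309.1 and CT025897.1 were -2.60 ± 0.35 and -4.25 ± 0.57 (SE), with 12 of 19 and 28 of 50 CT025897.1 UMIs in 1 cell of each stationary library. In cluster 33 CR848812.1 stood at 18.1 and 11.7 against 287 and 130.1 CPM, moving first. With the batch as a block edgeR called 56. Leaving out moving library 1 or 2 gave 540 or 4926 calls, and leaving out stationary library 1 or 2 gave 164 or 204.

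The last comparison tested whether the difference between conditions itself differed between the classes. The log2 fold change of ghrb was lower in glutamatergic-like than in GABAergic-like clusters by a difference of -3.62 ± 0.38 (SE, edgeR adjusted p = 0.0255, n = 2 libraries per condition). Its values were 3.50 ± 0.581 against 27.4 ± 1.01 CPM in the former and 5.39 ± 0.324 against 3.52 ± 1.27 CPM in the latter, moving first (SD). For nmu the difference was 2.57 ± 0.29 (edgeR adjusted p = 0.0327), from 69.9 ± 29.6 against 8.68 ± 0.339 CPM and 91.8 ± 72.2 against 62.0 ± 3.45 CPM. For c16h2orf66 it was -6.32 ± 0.64 (edgeR adjusted p = 0.0255), with 3508 of 3536 and 424 of 428 UMIs of the glutamatergic-like clusters of stationary libraries 1 and 2 in 1 cell each. Not passing, with an edgeR adjusted p of 0.113 each, were rgs4, a regulator of G protein signalling (1.32 ± 0.18), and the enkephalin precursor gene penka (1.21 ± 0.17).

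These were the 3 genes that edgeR called of 15960, with 695 at an unadjusted p under 0.05, and limma voom with the library as a correlated block called 1, ghrb. Of these, c16h2orf66 and nmu kept their call without the clusters lacking moving cells. Without the clusters lacking moving cells the difference of ghrb was -2.14 (edgeR adjusted p 0.849; 1.51e-16 to 0.849 over all alternatives and tools). Leaving out moving library 1 or 2 gave 28 or 97 genes, and leaving out stationary library 1 or 2 gave 12 or 22, with ghrb, nmu and c16h2orf66 called each time.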

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

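The test of a different response in the classes was planned, and the tests of single cells, of the class after clustering again and of the clusters lacking moving cells were chosen only after the result was seen.

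By a test of the difference itself, the change between conditions in glutamatergic-like clusters minus that in GABAergic-like clusters was -6.32 for c16h2orf66, -3.62 for ghrb and 2.57 for nmu on the log2 scale. With LOC100535857 and urp1 these were the 5 genes called within a class, in a single cluster or by the class test. A candidate explanation is that single cells hold most of the counts. Without the cell with the most UMIs in each library, 2 of the 5 genes kept under 50% of their log2 ratio, with at most 15.6% kept for urp1 and c16h2orf66. LOC100535857, ghrb and nmu kept 103%, 89.4% and 115%, which argues against 1 cell per library for them. Removing 1 cell cannot argue against a few cells, which was not tested for ghrb. In the glutamatergic-like clusters 1 cell held 75 of 183 and another 63 of 242 ghrb UMIs of stationary libraries 1 and 2. For nmu a few cells stay open, since 3 cells or fewer held 50% of its UMIs in the glutamatergic-like clusters of each moving library, and its values of -1.21 with the highest doublet scores removed and 0.83 without barcodes over 30000 UMIs went with at least 85.9% of those UMIs lying in kept cells that left the class when clustered again. The clusters lacking moving cells are argued against as the whole source for LOC100535857, since without them its log2 fold change was -4.13 ± 0.42 (SE), 82.3% of the log2 value with them. They still held much of its counts. Over all cells it stood at 27.7 and 30.1 CPM in stationary libraries 1 and 2, and at 13.4 and 12.3 CPM in their cells outside these clusters. The clusters stay open for ghrb, whose value of -2.14 ± 0.52 (SE) without them was within 2 SE of 50% of the value with them. A response to the patterns stays open as untested.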

How the results depend on the processing

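The highest doublet scores, barcodes over 30000 UMIs, clusters lacking moving cells, the crossed pairing, and the block and 1 library left out with estimated correlation are tests chosen after the data were seen. Keeping the 2 predicted doublets is the setting used throughout, so this choice gave no separate value. Apart from leaving out 1 library, 122 of 130 values of named genes in whole libraries, 89 of 106 in glutamatergic-like and 97 of 110 in GABAergic-like clusters, 10 of 15 in the class test and 7 of 10 in single clusters kept their direction and side of the threshold, as did 101 of 119 of lists and 435 of 455 of their example members. The spread between libraries limits whole-library calls: of simulated 2-fold changes edgeR recovered 0% at the estimated spread and 73.1% at a dispersion of 0.01.

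For whole libraries, DESeq2 called 47 genes and edgeR without a filter on low counts 3. For glutamatergic-like clusters DESeq2 called 26, no filter gave 23, and leaving out clusters lacking moving cells gave 0 in edgeR (210 at an unadjusted p under 0.05). For GABAergic-like clusters no filter gave 52. There edgeR called 0 with upper-quartile factors, the looser filter, the stricter filter, the highest doublet scores removed and without barcodes over 30000 UMIs, with 235, 231, 233, 234 and 235 at an unadjusted p under 0.05. The class test gave 133 without a filter and 1 with limma. Clustered without the genes at an unadjusted p under 0.05, which were taken from these same libraries, edgeR called 0 clusters in share (1 at an unadjusted p under 0.05). Camera passed 4 lists without the skin-like cluster (the mitochondrially encoded genes, calcium-binding proteins, clock genes and neuropeptides). Over all cells camera with an estimated correlation passed 0 and fry 0, each with 0 at an unadjusted p under 0.05. More genes enter without a filter; for the other changes the cause was not tested.

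With the batch as a block, edgeR called 6 genes in glutamatergic-like, 3 in GABAergic-like and 56 in single clusters, camera passed 2 lists, and with an estimated correlation beside the block 0. The block left the counts for whole libraries and cluster shares at 0 and 3, with 195 genes at an unadjusted p under 0.05. Medians reversed under the block for the unfolded protein response (-0.037), glycolysis (-0.013) and neurotransmitter genes (-0.018), with the same medians under the estimated correlation, and jun, gabrb4 and adcyap1b reversed to -0.0015, -0.012 and -0.0047. The crossed pairing gave 2 lists and 4 genes in glutamatergic-like clusters. Its reversed values were -0.037, -0.012 and -0.0092 for those lists and -0.0015, -0.011 and -0.0047 for those genes, and the cause was not tested.

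Other log2 fold changes that reversed were nmu in glutamatergic-like clusters (-1.21 with the highest doublet scores removed, where most of its moving UMIs lay in cells that left the class) and urp1 in GABAergic-like clusters (1.01 with the looser filter). The rest lay close to 0: adcyap1b was -0.0025 with the highest doublet scores removed, -0.0028 with the looser filter and -0.0081 without the skin-like cluster. It was -0.0057 with upper-quartile factors, -0.0095 without barcodes over 30000 UMIs and -0.0094 without clusters lacking moving cells. Without the skin-like cluster the glycolysis median was -0.00063 and gabrb4 was -0.0064, and gabrb4 was -0.0012 without barcodes over 30000 UMIs. For nkx1.2lb it was -0.060 with the stricter filter, -0.00098 with upper-quartile factors and -0.010 without clusters lacking moving cells. With a standardised makeup gapdhs, gabrb4 and nkx1.2lb were -0.027, -0.038 and -0.10. Apart from nmu, the cause was not tested.

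Leaving out 1 library leaves a lone library assumed to vary like those of the other group. The counts then ran from 0 to 44 genes in whole libraries, 3 to 4 clusters, 3 to 9 lists, 12 to 126 genes in glutamatergic-like and 2 to 668 in GABAergic-like clusters, 164 to 4926 tests in single clusters and 12 to 97 genes in the class test. List medians that reversed ran from -0.15 to 0.059 for immediate early genes, -0.46 to 0.17 for heat shock genes, -0.40 to 0.17 for the unfolded protein response, -0.057 to 0.071 for glycolysis, -0.044 to 0.22 for glutamate receptors, -0.047 to 0.19 for GABA-A and glycine receptors and -0.041 to 0.29 for voltage-gated channels. They also ran from -0.057 to 0.16 for calcium-binding proteins, -0.18 to 0.30 for presynaptic genes, -0.39 to 0.041 for neuropeptides, -0.27 to 0.34 for pretectal transcription factors, -0.29 to 0.099 for neurotransmitter genes and -0.15 to 0.36 for neuronal identity genes. With an estimated correlation 0 lists passed in each of these fits, and the medians were the same, such as without stationary library 1 -0.0050 for glutamate receptors, -0.0052 for GABA-A and glycine receptors, -0.040 for voltage-gated channels, 0.036 for neuropeptides and -0.063 for neurotransmitter genes. Example members that reversed ran from -0.34 to 0.77 for fosab, -0.35 to 0.32 for jun, -0.38 to 0.15 for scg2b, -0.79 to 0.21 for hsp90aa1.2, -0.016 to 0.18 for hsp70l, -0.40 to 0.43 for hspa5, -0.39 to 0.25 for xbp1, -0.086 to 0.10 for gapdhs and -0.13 to 0.26 for tpi1b. Others ran from -0.16 to 0.033 for atp5f1b, -0.46 to 0.61 for grin1b, -0.34 to 0.30 for gabrb4, -1.49 to 0.61 for scn1lab, -0.64 to 0.27 for scn1ba, -0.10 to 0.027 for calm2b, -0.22 to 0.18 for adcyap1b and -2.09 to 0.56 for agrp. The last ran from -1.05 to 0.29 for nfil3-5, -0.34 to 0.98 for zfhx4, -0.034 to 1.13 for tcf7l2, -0.22 to 0.26 for nkx1.2lb, -0.43 to 2.15 for mafaa, -0.29 to 0.57 for gad2, -0.14 to 0.58 for slc6a1a and -0.17 to 0.71 for elavl3. Fewer libraries enter these fits, and the cause was not tested further.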

Other observations

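The test of cell type makeup was written before its result was seen; the other tests here were chosen after.

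The 306 cells of the clusters lacking moving cells had higher levels of several genes than the other stationary cells; the genes were chosen after their values were seen and are given without a test. The bromodomain gene brd2a stood at 2235 and 1811 CPM in these cells against 324 and 312 CPM in the other cells of stationary libraries 1 and 2. Set out in the same order, the splicing factor gene srsf1b stood at 556 and 545 against 101 and 113 CPM and the arrestin family gene arrdc3a at 825 and 766 against 190.3 and 146 CPM. In the moving libraries brd2a stood at 379 and 221 CPM and srsf1b at 110.2 and 55.8 CPM. Immediate early genes together stood at 12344 against 11490.0 CPM in stationary library 1 and 12163 against 11224 CPM in stationary library 2. Among microRNA genes mir7a-1 stood at 2062 against 109.9 CPM, mir132-1 at 1053 against 141 CPM and mir135b at 575 against 70.8 CPM over both stationary libraries, these cells first. With at least 50 UMIs in stationary cells, 9 of 19 microRNA genes (47.4%) were raised at a 2-fold threshold, against 1.66% of all 15829 genes. Clustering on expression grouped these cells, and mir7a-1 is among the leading genes of cluster 47. Raised genes therefore follow in part from the grouping.

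Clusters 47, 53 and 54 held cells of both stationary libraries and of neither moving library. Damage that raises the mitochondrial share or leaves few UMIs is argued against among the kept cells. The higher ratio of median mitochondrial share to the other cells of a stationary library was 1.09, and the lower ratio of median UMIs was 1.03. The cell filters had already removed barcodes of high mitochondrial share or few genes, and damage of other kinds was not tested. A single contaminating type behind these clusters together is argued against too. Of their cells with at least 2 UMIs of the markers of 1 transmitter class and none of the other, 38 were glutamatergic and 31 GABAergic in stationary library 1. The counts were 60 and 80 in stationary library 2, so the smaller class held at least 42.9%, above each of 46 other clusters. Pooling adds to that mix, since clusters 53 and 54 were glutamatergic-like, and each of them alone may be of 1 type. In cluster 47 alone 45.4% of the cells held a glutamatergic and 60.6% a GABAergic marker. Of 25 clusters with at least 100 stationary cells, built without the genes at an unadjusted p under 0.05, 7 held none of these cells, which decides nothing about their source, since clustering itself set which cells were counted. Cells of a subset of the pooled larvae and a response to the stationary pattern stay open, both untested.

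Mitochondrially encoded genes were lower in the moving libraries by camera with a preset correlation (adjusted p 1.08e-16). The call was lost with an estimated correlation (camera adjusted p 0.733) and with fry (adjusted p 0.844), and edgeR called 0 members. A different makeup of cell types is argued against, since the median over 46 clusters of the log2 ratio of the moving to the stationary share was -0.67. Moving library 1 alone is argued against, since without it the median log2 fold change of the list was -0.60, with 11 of 12 genes lower. Other differences of handling between the conditions, which may differ in dissociation, and a biological effect of the moving pattern were not tested.

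A few genes, chosen after their values were seen, stood apart in single libraries. The gene zgc:158463 stood at 428 and 7124 CPM in the moving and 11262 and 5172 CPM in the stationary libraries. The muscle actin gene actc1b stood at 0.837 and 291 CPM in the moving and 0.270 and 0.606 CPM in the stationary libraries, and the keratin gene krt4 at 0.965 and 350.3 against 84.1 and 93.5 CPM. Barcodes over 30000 UMIs numbered 0 and 10 in the moving and 9 and 1 in the stationary libraries, and in moving library 2 and stationary libraries 1 and 2 they held 5.77%, 6.15% and 1.63% of the UMIs of the kept cells. Skin markers took 2.77%, 0.665% and 3.20% and microglial markers 0.161%, 0.259% and 0.267% of the UMIs of those barcodes.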
